A study of Manihot esculenta and Manihot esculenta subsp. flabellifolia with 6 samples.

How the data were processed

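The series holds 6 small RNA libraries, 1 for each combination of 3 genotypes (KU50, Arg7, W14) and 2 tissues (leaf, storage root). The deposited files give counts: each distinct read sequence of a library with its number of reads. The values are whole numbers and sequences seen once are kept. Adapter trimming, length limits and any other step before the counts are not given in the sources used here. Reads ran from 18 to 44 nt, and at least 97.4% of each library lay within 18 to 26 nt. No reference genome was used, so no tag has a genome position, and the origin of an unlisted tag was not tested.

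Library totals were 17448000 to 25088284 reads. Levels are RPM, the reads scaled to the library total. A count of 0 allows up to 3 reads, and intervals and such limits cover counting error only, since reads without molecular identifiers are not independent molecules.

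Reads of 19 to 24 nt were assigned to 39 mature small RNA families, with 11 passenger-strand families and 4 families of animals or monocots as controls for foreign reads. The family sequences were listed from general knowledge before the data were examined, as were the groups of families, tests, alternatives and naming rule, except where stated. A read joined the nearest family with a 5-prime offset of at most 2 nt, an overlap of at least 18 nt and at most 1 mismatch, and ties between families were left out. Members of near-identical families such as miR159 and miR319 are told apart only by this rule, and family sums can miss cassava members unlike the listed sequences. Of the 39 families, 8 were under the count minimum (miR391, miR472, miR482, miR2118, miR1446, miR2275, miR3627 and miR7122). The 2 monocot control families had at most 1 read per library. Fragments of rRNA and tRNA were exact substrings of listed sequences, and a plastid tRNA-His was added to that list after the data were seen. The list held the 5.8S, 5S and plastid 4.5S rRNAs and a few tRNAs, so other rRNA and tRNA fragments were not counted.

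Differences were tested on the counts with edgeR 4.0.16 in R 4.3.3, by the quasi-likelihood test with robust dispersion. The additive fit of genotype and tissue leaves 2 residual degrees of freedom. Dispersions were moderated across families or tags, so a p-value does not rest on those 2 degrees alone. For an edgeR log2 change, the SE is the absolute change divided by the square root of the F statistic. Tags of 18 to 26 nt and families were filtered with filterByExpr at a minimum count of 10. TMM factors from the filtered tags multiplied the library totals. The contrasts were root minus leaf, W14 minus the mean of KU50 and Arg7, and KU50 minus Arg7. Adjusted p-values are Benjamini-Hochberg values over the families or tags tested, with a threshold of 0.05. W14 is 1 genotype, so its contrast does not compare wild with cultivated plants in general. Groups of families were tested with camera (preset correlation 0.01) and fry. The genotype label links leaf to root: deviations from the tissue means correlated across tags at 0.81 in KU50, 0.82 in Arg7 and 0.79 in W14.

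The naming rule took every family past the threshold and then the most abundant, to 20 in all. It took 3 tags per direction with a mean of at least 50 RPM, the same direction throughout and no listed family, and within a tissue up to 10 families with at least a 4-fold difference and 10 RPM in the higher library. Sequences are not given for tags found with at least 5 reads in each library of 1 set and at most 3 reads in the other set, nor for a tag with a 16S-type rRNA segment, since they may come from another organism.

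The fit was tested on simulated counts with the tissue effect removed and known changes added. For root against leaf over 31 families, it recovered 95.0% of 64-fold and 40.8% of 8-fold changes, with 9 false calls among 380 unchanged values in 20 runs. For root against leaf over 183875 tags with 200 changed, it recovered 19.7% of 64-fold changes and none of the 4-fold or 16-fold ones, with 0 false calls. Both simulations used 1 common dispersion, and far fewer tags were changed than the 7954 called in the data. The shares recovered and the false calls therefore do not carry over to the data. Alternatives were other scalings (library totals, TMM over families, DESeq2 1.42.0 with its Wald test), limma-voom (limma 3.58.1), other mismatch and count limits, length shares over distinct tags, without rRNA and tRNA fragments or over all lengths, fits without the genotype term, and leaving out libraries or genotypes. Added after the data were seen were a term for the library set, leaving out tags that end in ATC or that occur in 1 set alone, and leaving out genotypes in the length comparison.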

Results

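Small RNAs were sequenced from fully expanded leaves and storage roots of cassava (Manihot esculenta), a tropical crop grown for its starchy roots. Sampling was at 150 days after planting, in field-grown plants without treatment. The plants were KU50 and Arg7, both cultivars, and W14, described in the labels as their wild progenitor. The deposited files of the KU50 and Arg7 samples carry other abbreviations than their labels, and genotypes are given here as labelled. Each of the 6 combinations of genotype and tissue had 1 library (n = 1), and the labels do not give the number of plants behind a library. The leaf libraries held 17648395 reads for KU50, 25088284 for Arg7 and 17448000 for W14. The root libraries held 21070793, 25012190 and 19464248 reads, in the same order. The 3 genotypes served as the replicates of the tissue comparison, and both tissues stood in for replicates in the genotype comparisons. Leaf and root of a genotype may come from the same plants, so the genotype comparisons do not cover the spread between plants of a genotype. The p-values thus measure only the spread between these libraries, which the fit pools in part across families or tags. Fragments of the plastid 4.5S rRNA were more abundant in leaf than in root of each genotype, at 1072 against 316 RPM (reads scaled to the library total) in KU50, 1734 against 481 in Arg7 and 2078 against 100.1 in W14. Fragments of a plastid tRNA-His, listed after the data were seen, were more abundant in leaf in KU50 (158556 against 11573 RPM) and Arg7 (4387 against 2536) but not in W14 (4556 against 4993). In Arg7 leaf, Arg7 root and W14 root, 29.1%, 46.2% and 42.4% of the reads of 28 to 44 nt ended in the bases ATC. That share was 0.564% in KU50 leaf, 0.278% in KU50 root and 0.362% in W14 leaf. These 2 sets of 3 libraries are called the tailed and the untailed set. KU50 against Arg7 is also a comparison between the sets, and the leaf and root of W14 lie in different sets.

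Leaf and root differed in the length of their small RNAs. Reads of 21 nt, the usual length of plant microRNAs, made up 37.3% ± 1.08 of the reads of 18 to 26 nt in leaf and 23.6% ± 6.62 in root (SD, n = 3 genotypes). Reads of 24 nt, the usual length of siRNAs that direct DNA methylation, made up 22.5% ± 6.22 in leaf and 34.7% ± 8.72 in root. The 22 nt share was 12.4% ± 1.45 in leaf and 18.6% ± 3.59 in root. Each of these differences had the same direction in the 3 genotypes. The 21 nt share had a root-minus-leaf difference of -4.89 percentage points in KU50, where it went from 36.1% to 31.2%, but went from 37.6% to 20.7% in Arg7 and from 38.1% to 18.9% in W14. Without the listed fragments of rRNA and tRNA, it went from 43.8% to 31.9% in KU50, and the 24 nt share there from 21.8% to 26.2%. In KU50 leaf, most of those fragments came from the plastid tRNA-His listed after the data were seen. The 24 nt share was 20.01% in W14 leaf and 42.4% in W14 root, against 17.9% and 25.2% in KU50 and 29.6% and 36.5% in Arg7. Each library of the tailed set thus had a higher 24 nt share than each of the untailed set, and without W14, whose libraries lie in different sets, the mean root-minus-leaf difference was 7.10 percentage points in place of 12.2. The first base differed as well. Of the 21 nt reads, 67.2% ± 1.93 began with T in leaf and 48.6% ± 6.58 in root. Of the 24 nt reads, 49.8% ± 2.26 began with A in leaf and 33.7% ± 4.46 in root. An exact sign-flip permutation test over 3 genotypes cannot give a two-sided p below 0.25, which is the value found for each of these 5 measures. When each distinct sequence was counted once, the common direction of the 24 nt share was lost: it was lower in root in KU50 (44.4% against 48.8%) and Arg7 (49.97% against 51.8%) and higher in W14 (59.2% against 48.7%), with a mean difference of 1.40 percentage points in place of 12.2. The 22 nt share and the share of 21 nt sequences starting with T also lost their common direction, through W14, with mean differences of 1.95 in place of 6.25 and -4.62 in place of -18.6. The 21 nt difference kept its direction, at -5.22 in place of -13.7.

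**Figure D1:**
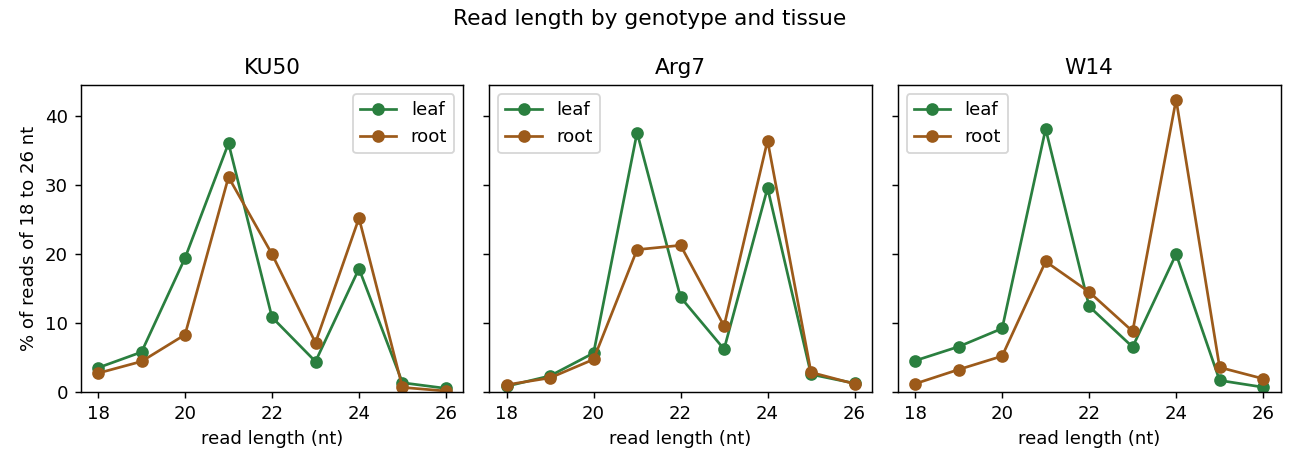
Share of reads of 18 to 26 nt (percent, vertical axis) at each read length (nt, horizontal axis) in leaf (green) and storage root (brown) of each genotype, with 1 library per line. The 24 nt peak is higher in root than in leaf in each panel, reaching 42.4% in W14 root, and the 21 nt peak is lower in root.

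The comparison of root with leaf asked which small RNA families differ between the storage organ and the leaf in all 3 genotypes alike. Of 31 families tested, 8 were lower in root and 1 was higher (edgeR quasi-likelihood test, Benjamini-Hochberg adjusted p under 0.05). The 3 families that act on copper proteins and laccases fell. miR408 fell from 269 ± 67.4 RPM in leaf to 6.57 ± 3.72 in root (SD, n = 3; log2 change -5.87 ± 1.17 SE, adjusted p = 7.58e-05). miR398 fell from 32.1 ± 8.58 to 0.638 ± 0.764 RPM (log2 change -6.66 ± 1.51, adjusted p = 0.000436). miR397 fell from 231 ± 111 to 15.4 ± 7.91 (log2 change -4.34 ± 1.14, adjusted p = 0.00168). Of the small RNAs that regulate auxin response factors, tasiARF and miR167 fell, while miR160 did not pass (log2 change -0.47 ± 1.24, adjusted p = 0.784). The trans-acting siRNA tasiARF went from 1002 ± 248 to 48.8 ± 16.2 RPM (log2 change -4.76 ± 0.71, adjusted p = 2.55e-07), and miR167 from 21014 ± 12707 to 839 ± 809 (log2 change -5.20 ± 1.29, adjusted p = 0.00110). miR827, of phosphate responses, went from 185 ± 46.4 to 5.64 ± 4.83 RPM (adjusted p = 0.00110). miR172, which acts on AP2-type transcription factors, went from 2605 ± 754 to 463 ± 332 (adjusted p = 0.00781). miR403, which acts on an ARGONAUTE gene, went from 178 ± 79.3 to 26.2 ± 24.1 (adjusted p = 0.0247). With reads identical to the listed sequences alone, miR167 had a log2 change of -2.37 ± 1.01 (adjusted p = 0.0703) and did not pass, nor did miR172 (-3.06 ± 1.32, adjusted p = 0.0703) and miR403 (-2.86 ± 1.497, adjusted p = 0.135). The 4 most abundant miR167 tags were not in the list. All 8 were lower in root in 3 of 3 genotypes. miR319, which acts on TCP transcription factors, was the family that rose past the threshold, from 5.24 ± 7.33 in leaf to 46.3 ± 34.3 RPM in root (log2 change 3.55 ± 1.39, adjusted p = 0.0439, higher in 3 of 3 genotypes), though it passed in 3 of 18 alternatives and not with a term for the library set.

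miR394, chosen after its values were seen, was at 6.68 ± 6.89 RPM in leaf and 120.4 ± 31.0 in root, higher in 3 of 3 genotypes, but did not pass (log2 change 4.40 ± 1.82, adjusted p = 0.0519). Among abundant families that did not pass, miR166, which acts on HD-ZIP III genes, was at 95278 ± 33002 RPM in leaf and 12003 ± 5993 in root (log2 change -3.50 ± 1.47, adjusted p = 0.0519). miR395, of sulfate assimilation, was at 159 ± 152 in leaf and 11.3 ± 1.67 in root (adjusted p = 0.0761). miR166 passed in 8 of 18 alternatives, miR395 in 7, miR858 in 5 and miR159 in 4. With a term for the library set all of these passed, with adjusted p-values of 0.000209, 0.00575, 0.00431 and 0.0147 in that order. Only W14 has libraries in both sets, so with that term the tissue change rests on KU50 and Arg7. In W14, miR858 and miR159 were higher in root, at 95.9 against 11.7 RPM and at 2198 against 235. miR156 was at 57560 ± 46047 in leaf and 31990 ± 35896 in root, and its relative miR535 at 5492 ± 2247 and 3467 ± 1777. Both act on SPL transcription factors. miR168 and miR162, which act on genes of the small RNA machinery, were at 2407 ± 355 and 120 ± 42.1 RPM in leaf and at 3602 ± 2201 and 61.2 ± 31.5 in root. miR159 was at 2210 ± 3319 in leaf and 1080 ± 1061 in root, and miR858 at 248 ± 359 and 41.2 ± 47.3. miR164, miR396 and miR169 were at 838 ± 419, 313 ± 24.2 and 95.1 ± 105 in leaf and at 1536 ± 856, 389 ± 188 and 189.5 ± 258 in root. For miR156, miR535, miR168, miR159, miR396 and miR162 the sign of the root-minus-leaf change depended on the scaling. Relative to the library totals, TMM scaling lowered root minus leaf by a mean of 0.37 on the log2 scale. It lowered root minus leaf in KU50 and Arg7 but raised it in W14. TMM computed over the families alone raised root minus leaf by a mean of 1.64 relative to the main scaling. No family then passed: tasiARF changed by -3.21 ± 1.61 SE and miR408 by -4.20 ± 1.78. The count also fell to 0 without Arg7 root, to 1 without KU50 root and to 2 without both Arg7 libraries, and rose to 14 without W14 leaf.

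**Figure D2:**
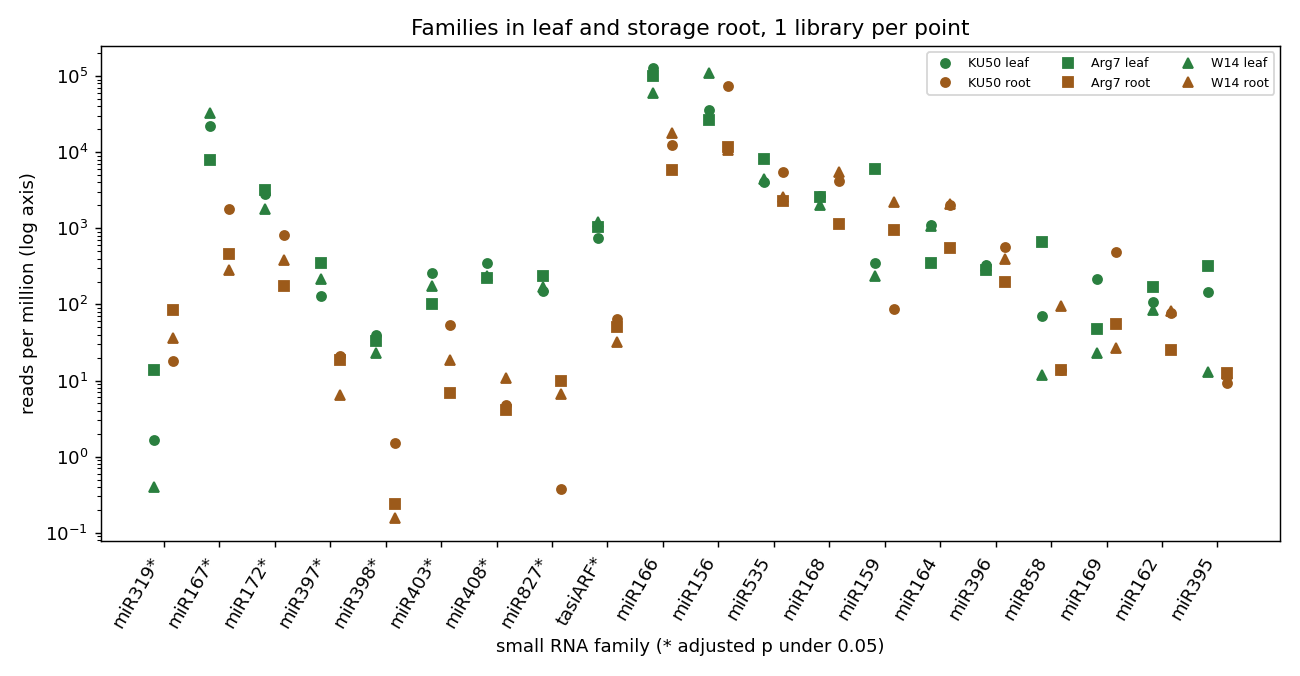
RPM (log axis) of the 20 named families in the 6 libraries, with 1 point per library; color gives the tissue and marker shape the genotype. For the 8 starred families lower in root, each leaf value lies above each root value, as for tasiARF with 737 to 1228 in leaf and 32.1 to 64.3 in root.

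Of the 7 groups of families listed beforehand, the copper and laccase group had 3 of 3 members lower in root. The auxin group had 2 of 5 members lower, and its other members, miR160, miR390 and miR393, did not pass. The group of phosphate, sulfate and nitrogen responses had 1 of 5 lower (miR827) and the small RNA machinery group 1 of 3 (miR403). The developmental transcription factor group had 1 of 10 lower (miR172) and 1 higher (miR319). None of the 4 tested members of the resistance gene and phased siRNA group passed, nor did any of the 4 other families. Adjusted over the list alone, the counts were the same except in 2 groups: miR319 no longer passed in the developmental group, and the other families had 1 higher (miR394) and 1 lower (miR530). The copper and laccase group moved one way on balance (fry adjusted p = 0.0106), as did the auxin group (fry adjusted p = 0.0370). Relative to the other families, no group passed in the camera test, with an adjusted p of 0.162 for copper and laccase (adjusted p = 0.673 with an estimated correlation). The developmental group had a median log2 change of -1.93 and a camera direction of up, because camera compares a group with the other families.

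Of 183875 tags, or distinct read sequences, 7954 differed between root and leaf, 3536 higher and 4418 lower in root. Of the higher tags, 42.6% were 22 nt long, against 20.5% of all tags tested, and 27.3% were 24 nt long, against 38.1%. Of the lower tags, 42.0% were 21 nt long, against 22.8% of all tags tested. ACATGGGAAATTTCTTGGCTG had 285, 75.1 and 85.8 RPM in root of KU50, Arg7 and W14 and at most 0.793 in leaf (adjusted p = 0.00166). A 21 nt tag, GGGACGGACTGGGAACGGCCC, had 191, 831 and 95.3 in root and 18.3, 14.1 and 11.2 in leaf (adjusted p = 0.0263). The third of the higher tags had a conserved segment of 16S-type rRNA, and its sequence is not given. CCATACTTTGAATTGTGGAAG had 163, 172 and 586 RPM in leaf and at most 0.807 in root. TCACAAGACAATTCAACCTAC had 113, 236 and 367 in leaf and at most 0.570 in root. TTGTCGCAGGAGCGGTGGCACC had 377 in KU50 leaf and 176 in Arg7 leaf, but 0.688 in W14 leaf, and at most 1.61 in root. These 3 tags each had an adjusted p of 0.00166. The last of them was nearest to the listed family miR3627, at 3 mismatches, past the limit of 1. With at most 2 mismatches, miR3627 had 494, 295 and 213 reads in leaf of KU50, Arg7 and W14. In root the family had 14, 10 and 10 reads, in the same order. The count of tags was 0 without the genotype term, and at most 2 when any 1 library of KU50 or Arg7 was left out. It was 59431 without W14 leaf (42022 higher) and 45644 without W14 root (19057 higher). The balance of higher and lower tags was thus not stable. In both fits the tissue change rests on the same KU50 and Arg7 libraries, since the remaining W14 library is taken up by its genotype term. A tissue change of W14 therefore cannot explain the difference in balance between these fits, and its cause was not tested. Scaling by library totals gave 8825 higher and 3613 lower.

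The comparison of W14 with the cultivars asked whether the wild progenitor differs from the mean of both in the same way in its leaf and its root. A family or tag could pass it by differing from 1 cultivar alone. No listed family passed in edgeR, and none had an unadjusted p under 0.05. DESeq2 called 1 family and limma-voom 0. The smallest adjusted p over the 31 families was 0.943, which covers the 20 most abundant (miR166, miR156, miR167, miR535, miR168, miR159, miR172, miR164, tasiARF, miR396, miR858, miR169, miR408, miR397, miR403, miR827, miR162, miR395, miR394 and miR6445). miR169 was at 23.2 RPM in W14 leaf and 27.1 in W14 root, against 215 and 487 in KU50 and 46.9 and 54.5 in Arg7. miR164 was at 1060 and 2061 RPM in W14 leaf and root, 1099 and 1998 in KU50, and 355 and 548 in Arg7. The group of phosphate, sulfate and nitrogen responses was lower in W14 relative to the other families (camera adjusted p = 0.0336). It did not pass in camera with an estimated correlation (adjusted p = 0.637) or in fry (adjusted p = 0.591). Of its members, 4 of 5 had a negative log2 change and 0 passed the threshold.

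Many single tags passed where no family did, but tags and families are not alike as features. The count filter keeps tags read in 1 genotype alone, which enter the test through the libraries where they are high. That can raise the count of tags called in the genotype comparisons. Families instead sum related sequences. Of 183875 tags, 91949 differed, 32970 higher and 58979 lower in W14, and 55.0% of the higher tags were 24 nt long, against 38.1% of all tags tested. The balance turned toward higher tags when any 1 library was left out. TTATATAGTAGTTCGTCTGAT had 421 reads in W14 leaf and 5627 in W14 root and 0 in the cultivars. CATTCATAGACTGTAGAAGCAT had 142 RPM in W14 leaf and 443 in W14 root, and 1 read in each Arg7 library. TATATAGTAGTTCGTCTGATAA had 358 and 6058 reads in W14 and 1 read in the cultivars. Each had an adjusted p of 1.12e-06. Of the tags lower in W14, TTCGATGAATGGACTGAACGG (adjusted p = 0.000194), AGTTAAGACCGTAGAACAGGCTAC (adjusted p = 1.02e-05) and TTTGGAACAAATGGGACTGCT (adjusted p = 9.81e-06) had 0 reads in both W14 libraries. The first had 1 read in Arg7 root, against 150 RPM in KU50 leaf, 42.3 in KU50 root and 141 in Arg7 leaf. The next had 8.10 and 129 RPM in KU50 leaf and root and 38.4 and 255.2 in Arg7. The last of them had 19.9 and 125 RPM in KU50 leaf and root and 68.3 and 114 in Arg7. The count was 0 in a fit by W14 or cultivar, which puts the differences between KU50 and Arg7 into the error. Leaving out a library gave 7400 higher and 2092 lower tags without KU50 root, 42366 and 6501 without Arg7 leaf, 31597 and 17354 without Arg7 root, and 28656 and 23053 without W14 root. It gave 54809 and 14322 without KU50 leaf, and 71517 and 64951 without W14 leaf. These fits tested 351808 to 434384 tags.

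Between KU50 and Arg7, no listed family passed in edgeR, DESeq2 or limma-voom, and 1 had an unadjusted p under 0.05 in edgeR. The smallest adjusted p was 0.530, over the same 31 families and the 20 named for W14. Among the tags, 17895 were higher in KU50 and 14358 in Arg7. With a term for the library set, 2055 tags passed, and 632 of them were shared with the first count. Only W14 has libraries in both sets, so that term measures its tissue change against that of the cultivars. It cannot separate set from genotype in this comparison. Of the 6 tags that the naming rule selected, 5 were found in the libraries of 1 set alone, and their sequences are not given. The other, TGAAGAAAGATGGTAATAACTC, had 299 RPM in KU50 leaf and 39.2 in KU50 root, 0.797 in Arg7 leaf and 0 in Arg7 root (adjusted p = 0.00174). TTCTATTGGTCTGGTGGTGTA, chosen after its values were seen, had 232 and 351 RPM in Arg7 leaf and root and at most 2 reads in each other library (adjusted p = 0.00174). The count was 0 without Arg7 leaf, 1 without either KU50 library, 164 without Arg7 root, 123461 without W14 leaf and 112964 without W14 root. Without W14 leaf, 75005 of the tags were higher in Arg7, so the balance turned.

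Within a tissue, libraries differed in the level of families, with no replicate and so no test; intervals are 95% exact Poisson intervals and cover counting error only. Arg7 leaf was the only tailed leaf library and KU50 root the only untailed root library, so genotype and library set cannot be told apart where these are compared with the others. Among the families named here, both libraries lay in 1 set only for miR394 and miR169 in leaf and for miR171, miR858 and miR399 in root. In leaf, 12 families differed at least 4-fold between the highest and lowest genotype. miR858 was at 661 RPM in Arg7 (651 to 671) and 11.7 in W14 (10.1 to 13.4). miR399, of phosphate responses, was at 112 in Arg7 (108 to 117) and 2.41 in W14 (1.73 to 3.25), and miR395 at 317 in Arg7 and 13.0 in W14. miR159 was at 6042 in Arg7 and 235 in W14, and miR319 at 13.7 in Arg7 and 0.401 in W14. miR394 and miR169 were 9.37-fold and 9.29-fold higher in KU50 than in W14. miR2111 and miR6445 were highest in Arg7, at 12.2 and 155 RPM, and miR160 was highest in KU50, at 56.2. In root, 14 families differed that much. miR477 was at 176 RPM in KU50 (170.0 to 181) and 4.06 in W14 (3.21 to 5.06). miR159 was at 2198 in W14 and 87.2 in KU50, and miR858 at 95.9 in W14 and 13.8 in Arg7. miR156 was at 73435 in KU50 and 10790.0 in W14, and miR167 at 1768 and 287. miR169 and miR399 were lowest in W14, at 27.1 and 2.83. miR390, miR171 and miR403 were lowest in Arg7, at 5.88, 2.04 and 6.80 RPM.

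Tags found with at least 5 reads in both members of a pair of libraries and in no other library were counted for each of the 15 pairs. Leaf and root of W14 alone shared 55957 tags, those of Arg7 31983 and those of KU50 21959. Both cultivar roots shared 9329 and both cultivar leaves 1558. Counted in the same way over 3 libraries, 1154 tags were in the untailed set alone and 1010 in the tailed set alone. The 3 leaf libraries alone shared 481, the 3 root libraries 95, and KU50 root with both Arg7 libraries 4242.

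**Figure D3:**
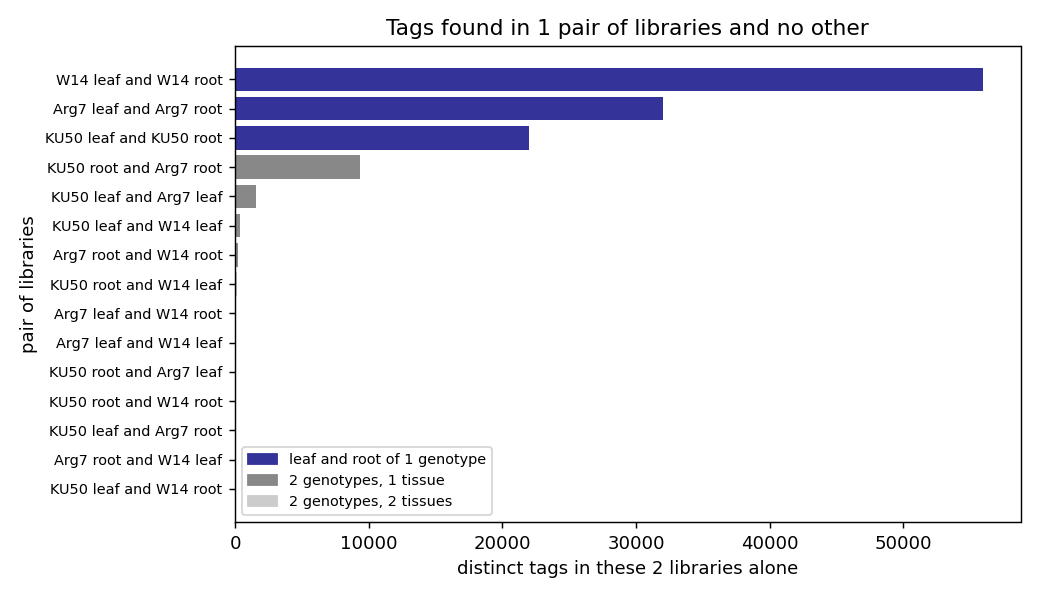
Number of tags (horizontal axis) found in both libraries of a pair and in no other library, for each pair (vertical axis). The pairs of leaf and root of 1 genotype hold 21959 to 55957 tags, and each pair of libraries from different genotypes holds at most 9329.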

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

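The tests of explanations in this part, with the term for the library set and the counts over other splits, were written down after the results were seen. Reads of 28 to 44 nt entered the family and tag comparisons only through the library totals and the definition of the sets. They ended in ATC 116235 times in Arg7 leaf, 111971 in Arg7 root and 112178 in W14 root, against 14 to 100 in the others. Reads matching animal microRNAs numbered 460 in Arg7 leaf, 485 in Arg7 root, 466 in W14 root and 413 in KU50 root, against 4 in KU50 leaf and 7 in W14 leaf. An adapter remnant on the plants' own reads was argued against, since at most 0.000195% of the reads of 3 abundant plant sequences carried the tail in these libraries. At least 93.6% of the animal reads ended in the tail in each of the 3 libraries, consistent with reads carried over from another small RNA library. The animal reads of KU50 root had no tail, so their source stays open, and no biological explanation was tested.

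Of the 10 splits of the 6 libraries into 3 and 3, which are too few for a share under 0.05, 1 gave as many families as the real one: the real split gave 9 and the highest other 0. For tags it was also 1 of 10, with 7954 and 1, and the 3 other splits that part all 3 genotypes gave 0, 0 and 1. Every other split leaves the real tissue difference at least partly in the error, which lowers its counts, so the splits decide nothing. With the set as a term, 8 of the 8 families lower in root passed. That argued against a difference between the tailed and untailed sets as their whole cause. By animal reads, however, KU50 leaf (4) also differed from KU50 root (413), while Arg7 leaf (460) and Arg7 root (485) were alike. A library difference along that mark was not tested. With the set term miR319 no longer passed, at a log2 change of 2.34 ± 1.29 SE (edgeR adjusted p = 0.143) in place of 3.55 ± 1.39. That was a smaller fold at a similar error. With scaling over the families alone, 0 of the 8 passed, and tasiARF went from -4.76 ± 0.71 to -3.21 ± 1.61, a smaller fold with a wider error. Scaling between tissues cannot be told apart from a fall of most families, because that scaling assumes that most families do not differ, and the tissue difference stays open.

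Among families with at least 10 RPM in a library, 5 had root-minus-leaf log2 differences of opposite sign and a size of at least 1 in a pair of genotypes; other families had opposite signs at smaller sizes or lower levels. Because miR159 and miR858 were higher in root in W14 alone, KU50 minus W14 was -5.24 for miR159 and -5.37 for miR858, and Arg7 minus W14 was -5.89 and -8.60. Only W14 spans both sets, so the set term measures its tissue change against that of the cultivars: it was 6.54 ± 1.86 SE for miR159 and 7.97 ± 2.16 for miR858 (edgeR adjusted p = 0.0209 for each). A difference between library sets predicts that Arg7 exceeds KU50 over 4 times in leaf and in root as well. miR159 met this, at 17.1 times in leaf and 10.9 times in root. miR858 met it in leaf, at 9.28 times, but not in root, at 0.989 times. Arg7 against KU50 is also a genotype difference, which could add to a set difference or offset it. Set and genotype therefore cannot be told apart for either family, and a difference between W14 and the cultivars stays open.

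For miR156, miR168 and miR2111 the set term did not pass (adjusted p = 0.391, 0.459 and 0.940), and differences between single genotypes were not tested in any family. For miR156, KU50 minus Arg7 was 2.23 and KU50 minus W14 was 4.40. For miR168, Arg7 minus W14 was -2.58. For miR2111, KU50 minus Arg7 was 3.54 and KU50 minus W14 was 3.07.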

How the results depend on the processing

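The term for the library set, the tests without tags that end in ATC or occur in 1 set alone, the length values without a genotype and the higher minimum for tags of 1 genotype were chosen after the data were seen. The 8 families lower in root had the same sign under all 18 alternatives, but none passed under all. tasiARF, miR398 and miR408 passed in 15, miR827 in 14, miR397 and miR403 in 12, and miR167 and miR172 in 11. miR319 passed in 3. These alternatives are not separate checks, and only 9 of them left no library out. Leaving out either or both libraries of a genotype rests the tissue change on the same other genotypes. The set term likewise rests it on KU50 and Arg7, as leaving out W14 does. The count of 9 families was 16 with DESeq2, 14 with limma-voom, 15 with at most 2 mismatches, 15 with the set term and 0 with TMM over the families, and 0 to 14 with libraries or genotypes left out. W14 against the cultivars gave 1 family with DESeq2 and 1 with at most 2 mismatches, and 0 to 1 with libraries left out (1 without KU50 leaf or W14 leaf). KU50 against Arg7 gave 0 to 1 (1 without W14 leaf). The camera call for W14 went from 1 group to 0 with an estimated correlation. Root-against-leaf tags (7954) numbered 12438 with library totals, 3510 with DESeq2, 0 without the replicate block, 34531 with the set term, 15192 without tags of 1 set alone, 12132 at a minimum count of 3, 1246 at 50, 13240 for 20 to 24 nt, and 0 to 59431 with libraries or genotypes left out. W14 tags (91949) numbered 46586 with DESeq2, 0 in the fit by W14 or cultivar, 169213 at a minimum count of 3, 15187 at 50, and 9492 to 136468 with libraries left out. KU50-against-Arg7 tags (32253) numbered 4322 with DESeq2, 2055 with the set term, 68773 at a minimum count of 3, 3430 at 50, and 0 to 123461 with libraries left out. Tag counts at other limits cover other numbers of tags, and fits without a library have fewer residual degrees of freedom; the cause of the other changes was not tested. Leaving out a genotype gave root-minus-leaf differences of -18.1 to -10.9 points for 21 nt, 4.81 to 8.33 for 22 nt and 7.10 to 14.9 for 24 nt. Counting distinct tags once gave root-minus-leaf differences of -5.22 points for 21 nt, 1.95 for 22 nt, 1.40 for 24 nt and -4.62 for 21 nt reads starting with T. Of these, only the 21 nt share kept 1 direction in the 3 genotypes: the 24 nt share was lower in root in KU50 and Arg7, and in W14 the 22 nt share went from 8.57% to 8.42% and the T share from 46.3% to 47.2%. No called family changed sign in these alternatives. Among uncalled ones, TMM over the families gave 0.35 for miR156, 0.55 for miR535, 1.59 for miR168, 0.86 for miR159, 1.41 for miR396 and 0.18 for miR162. miR168 was at 0.34 with library totals, 0.26 with DESeq2 and 0.35 without the block. miR396 was at 0.19 with library totals, 0.13 with DESeq2 and 0.33 with exact identity. With libraries or genotypes left out, the change was -3.21 to 0.51 for miR159, -0.12 to 0.82 for miR164, -1.10 to 0.96 for miR168, -0.19 to 0.62 for miR169, -0.74 to 0.46 for miR396 and -4.83 to 0.25 for miR858. Tags of 1 genotype alone numbered 21015, 11493 and 8296 at 10 reads for W14, Arg7 and KU50. Depth limits the rarest families, such as miR398 in root, which rested on 3 reads in W14 root.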

Other observations

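The isoforms and the tRNA fragment below were chosen after their values were seen; the test of single-base neighbours was not. The miR166 sequence TCGGACCAGGCTTCATTCCCG had 29352, 24552 and 13444 RPM in leaf of KU50, Arg7 and W14 and 329, 175 and 298 in root (log2 change -6.77 ± 1.08 SE, edgeR adjusted p = 0.00258). TCGGACCAGGCTTCATTCCCC, the most abundant miR166 sequence, had a log2 change of -3.34 ± 0.99 (adjusted p = 0.05003). The difference between both was not tested. A miR156 sequence, CTGACAGAAGATAGAGAGCAC, had 6.01 and 14.3 RPM in KU50 leaf and root, against 2501 and 467 in Arg7 and 1425 and 505 in W14. A fragment of the plastid tRNA-His, GGCGGATGTAGCCAAGTGGA, made up 136659 RPM of KU50 leaf and 1722 to 10142 in the other libraries.

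Of the tags found in both libraries of W14 and in no other library, 63.9% were 24 nt long, against 60.3% for Arg7 and 42.4% for KU50. The hypothesis that single-base differences between genotypes underlie part of these tags was set, with its prediction, before the test. Of the tags of 20 to 24 nt, 11.8% in KU50, 11.7% in Arg7 and 9.04% in W14 had a sequence that differed by 1 base, was present in the other genotypes and was absent from the own genotype. The share for tags of both cultivar roots was 1.82%, so the pooled share of the genotypes was 5.68 times higher, over the 2 times that the hypothesis predicted. The ratio is not corrected for the number of sequences that could be neighbours, which was 470621 for the cultivar roots, 550221 for Arg7, 716682 for KU50 and 1009094 for W14. For Arg7, with the number nearest to that of the cultivar roots, the ratio was 6.43. This is consistent with single-base differences between genotypes for a part of the tags, and most had no such neighbour.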
